A study of Mus musculus with 2 samples.

How the data were processed

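The measurement was droplet RNA sequencing of myeloid cells from regenerating mouse muscle. Per the labels' protocols, mice carrying Cx3cr1-creERT2, a tamoxifen-inducible Cre in cells that express the fractalkine receptor Cx3cr1, were given tamoxifen, and their tibialis anterior muscles were injured with notexin, a snake venom toxin that kills muscle fibres. The mice had either 1 functional and 1 null allele of the IFNγ receptor gene Ifngr1 (wt/null) or 1 floxed and 1 null allele (flox/null), and all 4 received a TNFα-neutralising antibody every day after injury. Per the labels' protocols, muscles were taken at day 5 or day 6 and digested with collagenase and dispase, and live CD45 and CD11b positive cells that were negative for Ly6G and SiglecF were sorted in 2 rounds. Cells of each mouse were tagged with hash antibodies against CD45 and MHC class I, pooled, and run with the 10x 3' v3 kit.

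Per the submitters' processing notes, Cell Ranger 5.0.0 and Seurat were used with the mouse builds mm10 and GRCm38.p5; the notes give no role or order for these tools and no Seurat version. The authors deposited raw UMI counts per feature and barcode as a filtered matrix of 32287 gene and transgene rows, 4 hash tag rows and 8755 barcodes. The values were checked to be whole numbers with no scaling. Gene locations came from GENCODE vM21 on GRCm38, in which 32235 of the 32287 gene rows (99.8%) were found by identifier.

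Barcodes were assigned to mice with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99, which gave 8035 barcodes with a single hash, 530 with more than 1 hash (6.05%) and 190 with none. A rule that instead placed a barcode on a hash holding at least 80% of its hash counts, with at least 50 hash counts, moved 0 cells to another hash, placed 131 that HTODemux did not, and left out 8 that it did. Cells with at least 500 genes and at most 10% mitochondrial counts were kept, which left 7597. Doublets between mice were removed by their hashes. Doublets within a mouse were scored with Scrublet in scanpy 1.11.5, whose own threshold called 0 of the 7597 cells, so it was not used to remove cells; above the score of the top 5% lay 165 of 513 hash doublets (32.2%).

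Clusters were computed with scanpy 1.11.5 on the 2000 most variable genes, leaving out the interferon, MHC and sex-linked lists, with 30 principal components and 15 neighbours. Cells were joined in a graph weighted by the share of neighbours they had in common (shares below 0.0667 were dropped), and Leiden clustering with igraph 0.11.9 at resolution 0.8 gave 14 clusters. An earlier clustering on a distance-weighted graph gave clusters that depended on the processor. The shared-neighbour graph replaced it for that reason, after the earlier results had been seen, and a distance-weighted graph computed at higher precision was kept as an alternative. A cluster was called X-like after the class whose fixed marker genes had the highest mean level, at least log2 0.5 above the mean of the clusters. At least 3 of these markers had to lie above that mean and be detected in at least 25% of cells. Leading genes were checked against the name only where the median UMI counts, relative to the cells' own mouse, were below 0.333.

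UMI counts were summed per mouse over the 6 clusters of monocyte-like, macrophage-like and resident macrophage-like cells (5960 cells) and separately within each cluster holding at least 50 cells from every mouse. Sums were tested with the edgeR 4.0.16 quasi-likelihood test after filterByExpr and TMM scaling, with day and genotype as terms, at a Benjamini-Hochberg adjusted p below 0.05 over 12214 genes. Every edgeR p-value therefore rests on 2 mice against 2 with 1 residual degree of freedom, and a genotype-by-day interaction could not be fitted. The median prior degrees of freedom that edgeR drew from all genes were 4.65 for the summed cells. DESeq2 1.42.0 was run beside it with the same terms. Fold changes are log2, flox/null over wt/null or day 6 over day 5, with the standard error of the fit. Levels in CPM are counts scaled to the total of each summed library, TMM-corrected.

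The 18 gene lists and 15 cell type marker lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. At the preset correlation camera sets the genes of a list against all other genes, so its p-values do not measure the spread between mice. With an estimated correlation it had only the 1 residual degree of freedom of the mice, so hardly any list could pass. Shares of cells carry exact (Clopper-Pearson) 95% intervals. Differences in shares between 2 mice and 2 mice were tested with the 2-sided exact permutation test, which cannot go below p = 0.333. Intervals cover counting error only, not differences between mice. Cluster shares were compared between groups only where no leading gene of the cluster was called between groups, a restriction added after the calls were seen.

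The edgeR steps were tested on simulated data with 200 changed genes. For the summed cells, over 12070 genes, the test recovered 7.46% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 100% of those changed 4-fold, with 1 unchanged gene among 117 calls and 0 calls when no gene was changed. For the largest dendritic-like cluster, over 8548 genes, it recovered 29.9%, 73.1% and 97.0%, with 10 unchanged genes among 143 calls and 0 calls when no gene was changed. The dendritic-like run with changed genes was fitted at 86.7 prior degrees of freedom, against 11.0 in the real cluster, so its recovery need not carry over. Simulated genes varied independently, with no day effect and no difference in cell mix between mice. The simulated spread between genes was revised once, after a first version had left it out.

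The comparisons, main tests, gene lists, markers and a set of alternative settings were fixed before the data were examined. The genes named are Ifngr1; for each contrast, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 10 CPM and the same sign in both pairs of mice or, with fewer than 10 calls, the 10 smallest p; up to 4 members per list, those past the threshold first and then those of highest CPM; and the 3 smallest p in each cluster. Other genes, such as list members with the largest changes and genes called by both edgeR and DESeq2, were chosen after their values were seen.

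Alternatives covered the test, the scaling, the count filter, the model terms, the hash rule, the cell filters, the cells summed, the clustering and each mouse left out in turn. Leaving out a mouse required a model without the term for the other factor, so a genotype difference then held part of the day difference, and the reverse. It leaves 1 mouse on 1 side, whose spread is taken to be that of the other mice. Cells with no hash or more than 1, low-quality cells and clusters of other cell types were left out of the sums. The day of a mouse goes with its cage-like identifier in the labels, so day cannot be told apart from litter or batch, and no mouse was without the TNFα antibody. Plots were drawn with matplotlib 3.10.9, and Python 3.11.15 and R 4.3.3 were used throughout.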

Results

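RNA of single myeloid cells was measured in injured tibialis anterior muscle of 4 mice, 1 per genotype and day: wt/null and flox/null at day 5, and wt/null and flox/null at day 6 after notexin. In flox/null mice, tamoxifen is meant to delete the remaining allele of Ifngr1, which encodes a chain of the IFNγ receptor, in cells of the Cx3cr1 lineage. The wt/null mice keep 1 functional allele. All 4 mice received an antibody against TNFα, so the comparison asks what IFNγ signalling to these cells adds while TNFα is blocked. The 8755 barcodes held a median of 12182 UMI counts (range 501 to 131142) and 2977 genes. After hash assignment and filters, 1625 cells came from wt/null day 5, 2048 from flox/null day 5, 1928 from wt/null day 6 and 1996 from flox/null day 6, with median UMI counts of 12048, 14505.5, 11934.5 and 11750. The summed monocyte- and macrophage-like cells numbered 1293, 1662, 1508 and 1497 and held 17486487, 26338792, 20316983 and 19652646 UMI counts. The hash antibodies bind CD45 and MHC class I, and the sort removed Ly6G and SiglecF positive cells.

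Macrophage-like cells made up most of the sort and fell into 4 clusters. Cluster 1 (1753 cells) was led by Gpr34, Selenop and Ms4a7 with the muscle transcripts Acta1, Mylpf and Myl1, cluster 2 (1793 cells) by the immediate early and stress genes Fosb, Fos, Atf3 and Gdf15, cluster 5 (1259 cells) by the matrix genes Mmp12, Spp1 and Fn1 with Gpnmb, and cluster 6 (392 cells) by the interferon-induced genes Ifit2, Ifit3, Cxcl10 and Rsad2. Cluster 9 (596 cells) was resident macrophage-like, with Cbr2, Cd163, F13a1 and Folr2, and cluster 4 (167 cells) was Ly6c-high monocyte-like, with Plac8, Hp, Ly6c2, Vcan and Chil3. Clusters 0 (734 cells, Cd209a and Klrd1) and 10 (192 cells, Ear2, Ccr2 and Mgl2) were like type 2 conventional dendritic cells (cDC2), cluster 12 (73 cells, Ccr7 and Fscn1) like migratory dendritic cells, cluster 11 (29 cells) like T or NK cells and cluster 13 (5 cells) like endothelial cells. Cluster 3 (216 cells) was led by the division genes Birc5, Top2a and Mki67, cluster 7 (230 cells) by Mmp9, Ctsk and Acp5, and cluster 8 (158 cells) had a median of only 1929 UMI counts; these 3 stayed unnamed. All names are rebuilt from markers, with no annotation of the study used here.

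The targeted gene Ifngr1 (ENSMUSG00000020009, GRCm38 chromosome 10, 19591949 to 19610229, a protein-coding gene) was at 218 CPM in wt/null day 5, 210 in flox/null day 5, 230 in wt/null day 6 and 220 in flox/null day 6. Its log2 fold change was −0.06 ± 0.08 (SE, 2 mice per genotype; edgeR adjusted p = 1.00). The 3' tags counted here need not come from the deleted part, so this level does not check the deletion. Transcripts of the CreERT2 transgene were found in all 4 mice, with 7, 12, 12 and 7 UMI counts over all cells. Xist, which silences an X chromosome in female cells, had 0, 1, 0 and 0 counts, and the Y-linked gene Ddx3y had 924, 1228, 964 and 1172, so the mice did not differ by sex.

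The flox/null genotype went with higher inflammatory genes and lower Tsc22d3 and Ddit4, but no gene passed edgeR's threshold over the summed cells. Il1b, the main cytokine of inflammasome activation, was higher at both days, log2 0.99 ± 0.11 (SE, 2 mice per genotype; edgeR adjusted p = 0.271), at 185 CPM in wt/null and 324 in flox/null at day 5 and 107 and 241 at day 6. Plac8, a gene of recently recruited monocytes, was higher by log2 1.52 ± 0.11 (adjusted p = 0.137; 34.0 and 109 CPM at day 5, 16.0 and 40.5 at day 6). It was the only gene of at least 10 mean CPM that was 2-fold or more higher at both days. With the same number of cells drawn per cluster in every mouse, Plac8 was higher by 0.46 and Il1b by 0.61. Tsc22d3 (also called GILZ), which glucocorticoids induce and which restrains NF-κB, was lower by log2 −0.85 ± 0.10 (adjusted p = 0.271; 289 and 147 CPM at day 5, 382 and 233 at day 6). Ddit4, a stress- and glucocorticoid-induced inhibitor of mTORC1, was lower by −1.40 ± 0.12 (adjusted p = 0.186; 12.4 and 4.77 CPM, then 13.1 and 4.90). Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA, was higher by 2.11 ± 0.17 (adjusted p = 0.137; 2.58 and 13.1 CPM, then 3.17 and 11.8). On GRCm38, the protein-coding genes Il1b (ENSMUSG00000027398) and Cdk5rap1 (ENSMUSG00000027487) lie on chromosome 2 at 129364570 to 129371139 and 154335380 to 154373010, and Plac8 (ENSMUSG00000029322) on chromosome 5 at 100553725 to 100572245. Tsc22d3 (ENSMUSG00000031431) lies on chromosome X at 140539528 to 140600659 and Ddit4 (ENSMUSG00000020108) on chromosome 10 at 59949669 to 59951834.

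The other 5 genes with the smallest p did not pass edgeR's threshold either. They were the serine protease inhibitor Serpina3g (1.36), the TGFβ-family ligand Gdf3 (0.83), the TGFβ decoy receptor Bambi (0.89) and the Y-chromosome gene Gm21860 (1.26), all higher, and the long noncoding RNA E230001N04Rik (−1.78), which lies on chromosome 17 at 28522720 to 28525398, beside the glucocorticoid-induced gene Fkbp5. Serpina3g belongs to a family of near-identical genes, so its counts are uncertain. edgeR called 0 of 12214 genes and had 385 at an unadjusted p below 0.05, whereas DESeq2 called 11, of which 9 rose and 2 fell. These 385 were 3.15% of the tested genes, a smaller share than a threshold of 0.05 gives on average when no gene differs. DESeq2's rises included Plac8 (adjusted p = 1.1e-10), Cdk5rap1 (7.1e-06), Il1b (7.1e-06), the interferon-induced chemokine Cxcl10 (0.92, adjusted p = 3.2e-04) and the monocyte and T cell chemokines Ccl4 (0.87, 0.00535) and Ccl2 (0.83, 0.0168). Its falls were Tsc22d3 (1.4e-04) and Ddit4 (0.0143). Leaving out flox/null day 6 raised edgeR's count to 59, leaving out flox/null day 5 raised it to 9, and leaving out wt/null day 6 raised it to 1.

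**Figure D1:**
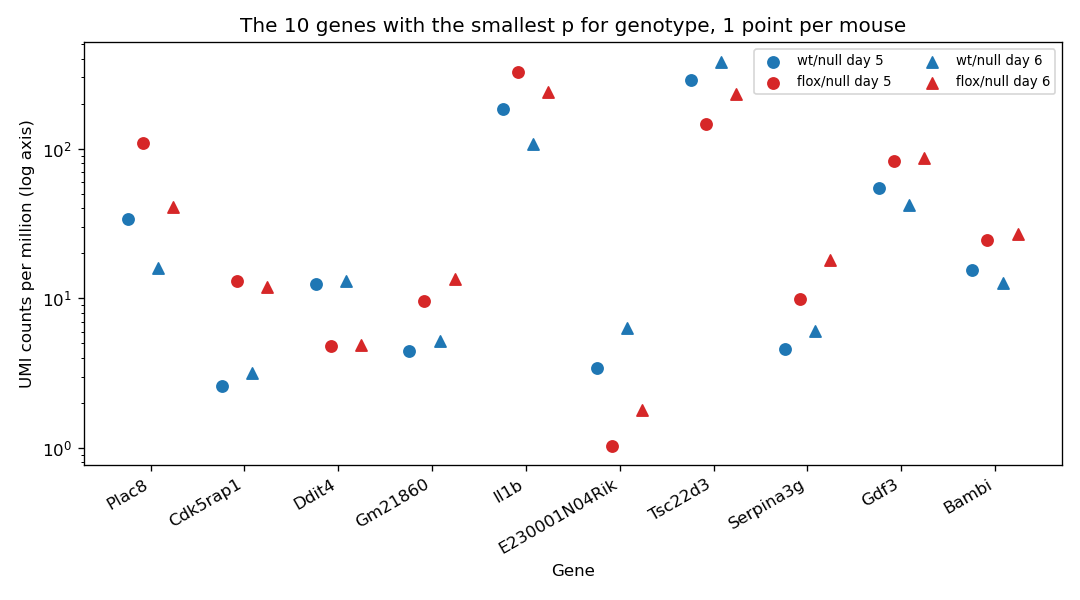
UMI counts as CPM (vertical log axis) in summed monocyte- and macrophage-like cells for the 10 genes with the smallest p for genotype; each point is 1 mouse, blue wt/null, red flox/null, circles day 5 and triangles day 6. Il1b was at 185 and 107 in wt/null and 324 and 241 in flox/null, and Tsc22d3 at 289 and 382 in wt/null and 147 and 233 in flox/null.

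The list of pro-inflammatory cytokines and chemokines was higher in flox/null mice: all 18 measured members were higher over both days (median log2 0.73; camera adjusted p = 1.9e-11), 0 passed over all genes and 11 passed when adjusted over the list alone. The list's adjusted p was 0.988 with an estimated correlation, which was −0.0065 and left the test 1 residual degree of freedom. Among its members were the cytokine Tnf (0.75 ± 0.12), the chemokines Ccl3 (0.54 ± 0.13) and Cxcl2 (0.71 ± 0.26), which draw monocytes and neutrophils, and the prostaglandin enzyme Ptgs2 (0.50 ± 0.15). Of these genes, 14 were higher at each day taken alone, with list medians of 0.49 at day 5 and 0.94 at day 6. With each mouse left out in turn the list stayed higher, with adjusted p from 1.5e-16 to 0.0176.

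IFNγ-induced genes were not lower in flox/null mice. As a list they were slightly higher, with 28 of 33 members higher (median log2 0.14; camera adjusted p = 6.5e-05), 0 past the threshold over all genes and 4 past it adjusted over the list alone. Their adjusted p was 0.988 with an estimated correlation. The chemokines Cxcl10 (0.92 ± 0.14) and Cxcl9 (1.45 ± 0.34), which attract activated T cells, the cytokine signalling inhibitor Socs1 (0.97 ± 0.15) and the checkpoint ligand gene Cd274 (0.46 ± 0.10) were the highest among members of at least 10 mean CPM. Cxcl9 went both ways within macrophage-like clusters. It rose in cluster 1 by 2.10 ± 0.40 (edgeR adjusted p = 0.00902; 3.28 at day 5 and −0.12 at day 6), and was lower in cluster 2 by −0.99 ± 0.44 (0.999) and in cluster 5 by −2.96 ± 0.43 (0.104). DESeq2 gave the rise in cluster 1 an adjusted p of 1.00. The list median was 0.40 at day 5 and −0.07 at day 6, and without wt/null day 5 it was 0.00 (adjusted p = 0.773). MHC class II genes, which IFNγ raises through Ciita, had a median of −0.02 with 3 of 10 higher (adjusted p = 0.923), with Cd74 at −0.02 and H2-Aa at −0.03, and none passed adjusted over the list alone.

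Stress and monocyte genes were the other lists past camera's threshold for genotype. Immediate early and heat shock genes, which tissue digestion can induce, were higher for 15 of 16 members (median 0.33; adjusted p = 6.4e-05; 0 adjusted over the list alone), among them Fos (0.44), Jun (0.37) and Hspa1a (0.35); their median was 0.02 at day 5 and 0.56 at day 6. Genes of Ly6c-high monocytes were higher for 11 of 13 (median 0.74; adjusted p = 1.3e-04; 7 adjusted over the list alone), among them Hp (1.11 ± 0.25), Vcan (1.22 ± 0.38), Ly6c2 (0.88 ± 0.25) and Chil3 (0.79 ± 0.26). Both lists had an adjusted p of 0.988 with an estimated correlation. The monocyte list's median was 0.85 at day 5 and −0.07 at day 6. It was −0.33 without flox/null day 5 and 0.44 without wt/null day 6, in fits with no day term that also hold part of the day difference. With the same cells per cluster in every mouse the monocyte list's median was 0.18 (camera adjusted p = 0.467). The stress list lost its call without wt/null day 6 (median 0.07, adjusted p = 0.671). Marker genes ran alike, with Ly6c-high monocyte markers higher (median 0.77, 9 of 10, adjusted p = 2.1e-05, 7 adjusted over the list alone) and resident macrophage markers lower (−0.23, 8 of 9, adjusted p = 1.9e-04, 1 adjusted over the list alone). Both marker lists had an adjusted p of 0.747 with an estimated correlation.

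**Figure D2:**
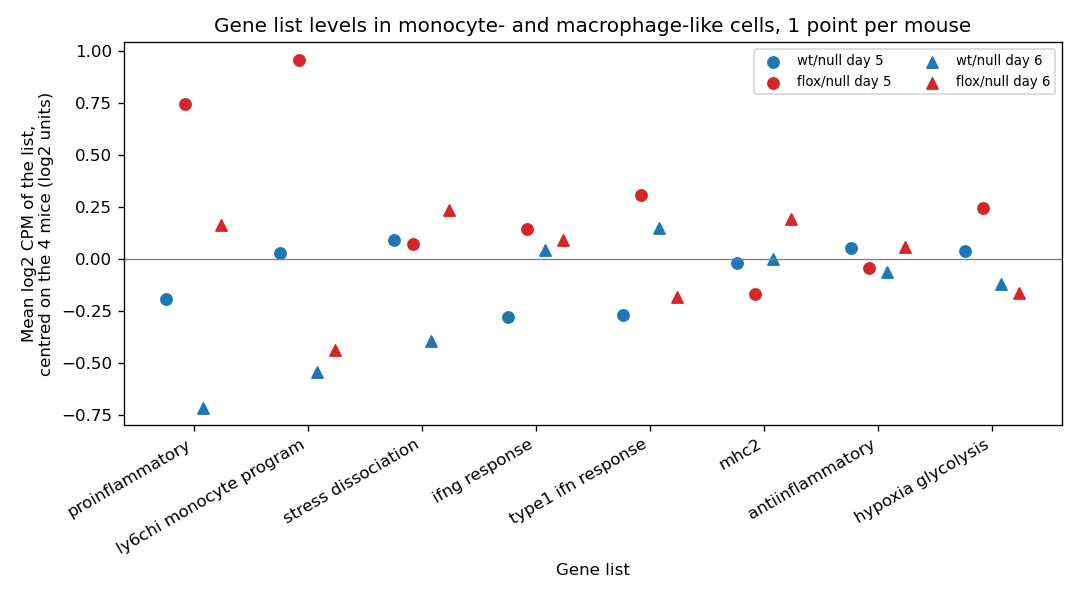
Mean log2 CPM of each gene list, centred on the 4 mice (vertical axis, log2 units), for 8 lists (horizontal axis); each point is 1 mouse, blue wt/null, red flox/null, circles day 5 and triangles day 6. For the pro-inflammatory list each flox/null mouse lies above the wt/null mouse of its day, whereas for type I interferon genes the order differs between day 5 and day 6.

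The remaining 14 lists did not pass camera's threshold for genotype. Genes of the anti-inflammatory state had a median of −0.08 with 6 of 19 higher (adjusted p = 0.449), repair growth factors 0.11 (0.496), Trem2 and lysosomal lipid genes −0.01 (0.979), and matrix and fibrosis genes 0.08 (0.318). Type I interferon genes had 0.14 (0.213), MHC class I genes 0.02 (0.693), TNFα and NF-κB targets 0.09 (0.158), complement and efferocytosis genes −0.06 (0.213), cell cycle genes 0.09 (0.158), hypoxia and glycolysis genes 0.07 (0.449), and IFNγ receptor genes 0.02 (0.979). Muscle and blood transcripts had 0.25 (0.837) and sex-linked genes 0.04 (0.876).

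Within clusters the fall of Tsc22d3 passed the test in 4 of 5 clusters and Ddit4 in the same number. Tsc22d3 fell in cluster 1 by log2 −0.996 ± 0.080 (SE, 2 mice per genotype; edgeR adjusted p = 6.5e-09), in cluster 2 by −0.88 ± 0.08 (0.00682), in the resident macrophage-like cluster 9 by −1.12 ± 0.18 (9.3e-04) and in the cDC2-like cluster 0 by −1.03 ± 0.14 (0.0108). In the Spp1 and Mmp12 cluster 5 it was lower by −0.62 ± 0.07 (adjusted p = 0.0808). Ddit4 fell in cluster 2 by −1.90 ± 0.19 (0.00682), in cluster 9 by −2.66 ± 0.40 (2.7e-04), in cluster 0 by −1.40 ± 0.17 (0.00619) and in cluster 1 by −1.52 ± 0.31 (0.0167). DESeq2 also called Tsc22d3 in clusters 0, 1 and 2, but Ddit4 in cluster 2 alone (adjusted p = 0.0401). It gave Ddit4 an adjusted p of 1.00 in clusters 1 and 9 and none in cluster 0, and Tsc22d3 1.00 in cluster 9. Cdk5rap1 rose in cluster 1 by 2.20 ± 0.27 (2.4e-05) and in cluster 2 by 2.16 ± 0.28 (0.0253), and DESeq2 called it in neither.

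Inflammatory genes rose within several clusters. In resident macrophage-like cells (cluster 9) the chemokines Cxcl10 (log2 1.77 ± 0.17, edgeR adjusted p = 2.4e-07; 91.6 and 233 CPM at day 5, 68.1 and 312 at day 6) and Cxcl2 (1.23 ± 0.15, adjusted p = 1.5e-05) rose. Retnla, a gene of alternatively activated macrophages, fell there by −3.55 ± 0.36 (adjusted p = 5.6e-07; 252 and 50.6 CPM at day 5, 267 and 1.23 at day 6, the last from 2 counts), and DESeq2 gave it an adjusted p of 1.00. In cDC2-like cells (cluster 0) Il1b rose by 1.38 ± 0.13 (adjusted p = 0.00128; 1057 and 2463 CPM, then 577 and 1671), the activation marker Cd83 rose by 0.88 ± 0.12 (0.0108), Plac8 rose by 1.26 ± 0.15 (0.00619), and Ccl17, a chemokine for type 2 helper T cells, fell by −3.31 ± 0.38 (0.00619), with no adjusted p from DESeq2. In cluster 2 Ccl4 rose by 0.72 ± 0.08 (0.0165) and Il1b by 0.69 ± 0.08 (0.0174), and in cluster 1 Ccl3 rose by 0.97 ± 0.12 (2.4e-05). DESeq2 gave Ccl3 in cluster 1 an adjusted p of 1.00 and Plac8 in cluster 0 none; the rises of Cxcl10, Cxcl2, Il1b, Cd83 and Ccl4 named here were also called by it. In cluster 5 the antimicrobial enzyme gene Lyz1 fell by −1.06 ± 0.07 (0.00200; 612 and 300.6 CPM, then 618 and 291), while Rsad2 was higher by 0.91 ± 0.12 (0.0808). Lyz1 has a near-identical neighbour, Lyz2, with which reads can be shared.

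**Figure D3:**
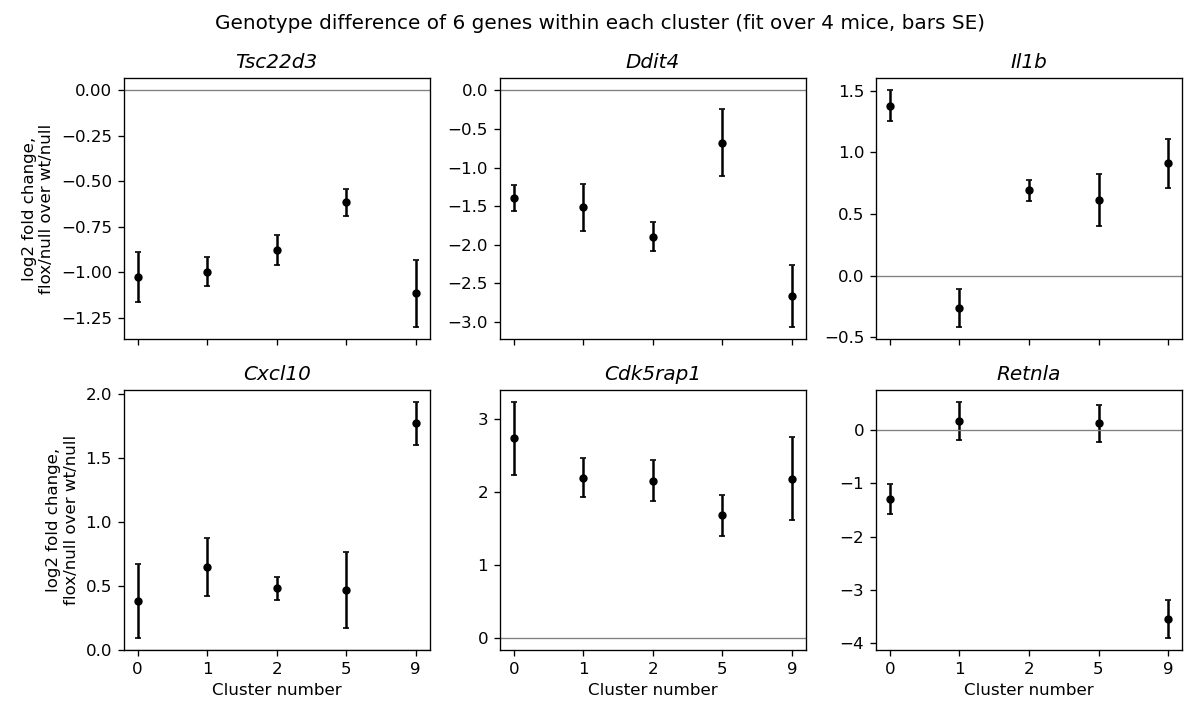
Genotype log2 fold change (flox/null over wt/null, vertical axes) of 6 genes within each tested cluster (horizontal axes, cluster number); points are fits over 4 mice and bars are standard errors. Tsc22d3 lay between −0.62 and −1.12 in all 5 clusters, and Retnla was at −3.55 in cluster 9.

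Across the 5 clusters tested, edgeR called 19 genes in cluster 0, 40 in cluster 1, 7 in cluster 2, 1 in cluster 5 and 28 in cluster 9, of which DESeq2 also called 7, 1, 4, 1 and 2. Without wt/null day 6 these counts were 7, 5, 4, 0 and 6, without flox/null day 6 they were 206, 162, 118, 42 and 71, without flox/null day 5 they were 86, 79, 72, 20 and 51, and without wt/null day 5 they were 85, 18, 8, 2 and 15. The pro-inflammatory list was higher in all 5 clusters, most in cluster 9 (10 of 10 members, median 0.92, camera adjusted p = 8.4e-11; 9 adjusted over the list alone), where the adjusted p was 0.754 with an estimated correlation. Its camera adjusted p was 0.00191 in cluster 0 (11 of 13 members higher) and 0.00550 in cluster 1 (8 of 12). It was 3.7e-08 in cluster 2 (13 of 15) and 0.00353 in cluster 5 (13 of 16). With an estimated correlation these adjusted p were 0.801, 0.970, 0.888 and 0.977. In cluster 0 only 5 of 13 members were higher at each day taken alone. The list's median in cluster 1 was 0.10 at day 5 and 0.92 at day 6, and Il1b was lower there (−0.26 ± 0.15).

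Other lists passed camera's threshold within clusters too. IFNγ-induced genes were higher in cluster 0 (19 of 26 members, median 0.23, camera adjusted p = 0.00653; 3 adjusted over the list alone), cluster 1 (26 of 31, 0.12, 9.8e-04; 3), cluster 2 (27 of 31, 0.17, 0.00229; 2) and cluster 9 (21 of 27, 0.20, 6.5e-04; 1). With an estimated correlation these had an adjusted p = 0.801, 0.970, 0.888 and 0.754. Their medians were 0.50, 0.42, 0.54 and 0.43 at day 5 but −0.02, −0.05, −0.03 and 0.05 at day 6, so they rest on the day 5 pair of mice. Type I interferon genes were higher in cluster 1 for 21 of 21 members (median 0.29, camera adjusted p = 4.5e-06; 7 adjusted over the list alone) and in cluster 0 for 17 of 20 (0.15, 0.0145; 1). With an estimated correlation these had an adjusted p of 0.970 and 0.801; their medians were 0.57 and 0.52 at day 5 and 0.07 and −0.01 at day 6. In cluster 0 MHC class I genes (15 of 15, 0.21, camera adjusted p = 0.00161; 1 adjusted over the list alone) and TNFα and NF-κB targets (14 of 17, 0.21, 0.00317; 4) were also higher, both with an adjusted p of 0.801 with an estimated correlation. In cluster 5 Ly6c-high monocyte genes were higher beside the pro-inflammatory genes (10 of 12, 0.46, camera adjusted p = 0.00353; 6 adjusted over the list alone), with medians of 0.48 at day 5 and 0.07 at day 6, and so were cell cycle genes (0.22, 0.0477; 0). Both had an adjusted p of 0.977 with an estimated correlation.

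Stress genes were higher beside the inflammatory genes in cluster 0 (16 of 16, median 0.25, camera adjusted p = 0.00161; 7 adjusted over the list alone), cluster 2 (adjusted p = 0.0218; 0 adjusted over the list alone), cluster 5 (0.00378; 3) and cluster 9 (0.0462; 0). Muscle and blood transcripts were higher in cluster 9 for 5 of 5 members (0.48, adjusted p = 0.00228; 4 adjusted over the list alone). With an estimated correlation these had an adjusted p = 0.801, 0.888, 0.977, 0.754 and 0.754. In cluster 9 the stress genes went opposite ways, with a median of −0.32 at day 5 (1 of 16 higher) and 0.66 at day 6 (16 of 16). Their medians at day 5 and day 6 were 0.13 and 0.36 in cluster 0, 0.18 and 0.15 in cluster 2 and 0.01 and 0.39 in cluster 5. Differences between clusters were not tested.

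From day 5 to day 6, genes of recruited monocytes and of inflammation were lower and MHC class II genes were higher, with no gene past edgeR's threshold. Plac8 was lower by log2 −1.27 ± 0.11 (SE, 2 mice per day; edgeR adjusted p = 0.382), the secreted protease inhibitor Slpi by −2.0 ± 0.20 (0.382), the cell cycle and complement response gene Rgcc by −0.97 ± 0.10 (0.382) and the surface glycoprotein gene Cd24a by −1.83 ± 0.21 (0.475). The macrophage growth factor Csf1 was lower by −1.08 ± 0.14, the small heat shock gene Hspb1 by −1.03 ± 0.14 and Tmem64 by −1.13 ± 0.16. The metalloprotease Adam19 (0.87 ± 0.12), Shisa9 (1.38 ± 0.19) and the noncoding RNA E130102H24Rik (0.87 ± 0.12) were higher, all with an adjusted p of 0.475. Plac8, Slpi, Cd24a, Ly6c2 and Chil3 were at least 2-fold lower in both genotypes. All of these but Cd24a are leading genes of the Ly6c-high monocyte-like cluster 4, which was part of the sums. For them, and for the lists of monocyte genes, fewer such cells and lower levels within cells are not told apart here. edgeR called 0 genes and had 858 at an unadjusted p below 0.05, while DESeq2 called 16, with 14 falls such as Plac8 (adjusted p = 8.7e-07), Slpi (6.9e-06) and the chemokine receptor Ccr1 (−1.14, 1.9e-04) and 2 rises, the adhesion genes Vcam1 (0.87, 0.0278) and Cadm1 (0.83, 0.0422). Without flox/null day 6 edgeR called 103 genes, without wt/null day 5 it called 68, and without wt/null day 6 it called 2. Day goes with the cage in the labels, so these differences and those of litter or batch cannot be told apart.

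By list, Ly6c-high monocyte genes were lower at day 6 for 12 of 13 members (median log2 −0.81; camera adjusted p = 5.7e-06; 9 adjusted over the list alone), pro-inflammatory genes for 18 of 18 (−0.64; adjusted p = 6.3e-06; 6 adjusted over the list alone) and glycolysis and hypoxia genes for 12 of 13 (−0.29; adjusted p = 6.8e-04; 2 adjusted over the list alone). These 3 lists had an adjusted p of 0.840 with an estimated correlation. Their members included Vcan (−2.81 ± 0.40), Ly6c2 (−1.61 ± 0.26) and Chil3 (−1.60 ± 0.26), Ccl2 (−0.94 ± 0.14) and Clec4e (−1.19 ± 0.23), and Gapdh (−0.37 ± 0.12) and Vegfa (−0.82 ± 0.13). Of the pro-inflammatory genes, 10 of 18 were lower in both genotypes. Matrix genes were lower (−0.16, 12 of 19; adjusted p = 0.0348, and 0.840 with an estimated correlation; 10 adjusted over the list alone), with Spp1 at −0.90 ± 0.25 and Fn1 at −0.75 ± 0.24 and the elastase Mmp12 higher at 0.53 ± 0.10. Cell cycle genes (−0.13, adjusted p = 0.0212) and stress genes (−0.14, adjusted p = 0.0348) were also lower, and MHC class II genes (0.26, 8 of 10; adjusted p = 0.0286) and IFNγ-induced genes (0.10, 22 of 33; adjusted p = 0.0348) were higher. These 4 lists also had an adjusted p of 0.840 with an estimated correlation, and none had a member past the threshold adjusted over the list alone; Cd74 was at 0.33 ± 0.14 and H2-Aa at 0.36 ± 0.15. From day 5 to day 6 the stress genes had a median of −0.48 in wt/null (0 of 16 higher) but 0.21 in flox/null (11 of 16), and IFNγ-induced genes had 0.28 (29 of 33) but −0.12 (11 of 33), so these 2 lists did not go the same way in both genotypes. Pro-inflammatory genes lost their call without wt/null day 6 (adjusted p = 0.446) and MHC class II genes without flox/null day 6 (0.158). Matrix genes lost theirs without wt/null day 5 (0.189) or wt/null day 6 (0.290), and cell cycle genes without wt/null day 5 (0.0681), flox/null day 5 (0.0752) or wt/null day 6 (0.0967). IFNγ-induced genes had a median of −0.07 without wt/null day 5 (adjusted p = 0.194) and lost their call without wt/null day 6 (0.212) or flox/null day 6 (0.158). Stress genes had a median of 0.25 without wt/null day 6 (0.0751) and lost their call without wt/null day 5 (0.189) or flox/null day 5 (0.139). Of the marker lists, Ly6c-high monocyte genes were lower (−1.23, 9 of 10; adjusted p = 4.0e-05; 8 adjusted over the list alone) and so were 3 endothelial genes (−0.84; adjusted p = 0.00745; 1 adjusted over the list alone), while 2 eosinophil genes were higher (0.70; adjusted p = 0.0332; 0 adjusted over the list alone). These 3 marker lists had an adjusted p of 0.647 with an estimated correlation.

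The remaining 10 lists did not pass camera's threshold for day. Medians were −0.07 for type I interferon genes (adjusted p = 0.855), −0.06 for MHC class I genes (0.353), 0.02 for IFNγ receptor genes (0.693), 0.00 for TNFα and NF-κB targets (0.315), 0.10 for anti-inflammatory genes (0.316) and −0.06 for repair growth factors (0.523). They were −0.03 for Trem2 and lysosomal lipid genes (0.937), 0.09 for complement and efferocytosis genes (0.281), 0.17 for muscle and blood transcripts (0.272) and 0.11 for sex-linked genes (0.281).

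Most single genes did not differ between genotypes the same way at day 5 and day 6. Across 7140 genes of at least 10 mean CPM, the genotype difference at day 5 and that at day 6 had Pearson's r = −0.0977 and Spearman's rho = −0.180, and 43.3% had the same sign; these are correlations across genes, which are not independent replicates. Type I interferon genes were an example, with Isg15 higher in flox/null at day 5 (log2 0.79) and lower at day 6 (−0.37) and Ifit3 at 0.74 and −0.30. For the day difference within each genotype r was 0.182, rho 0.186 and the same sign was seen for 57.0%. Each of these values sets 1 mouse against 1 mouse, and the difference between days was not tested.

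Sizes could be compared for only a few clusters, because 1 to 3 of the 10 leading genes of each other cluster were called between groups in the summed cells or in a cluster. The dividing cluster 3 held 3.08% (exact 95% interval 2.29 to 4.04) of cells in wt/null day 5, 4.10% (3.28 to 5.05) in flox/null day 5, 2.54% (1.89 to 3.35) in wt/null day 6 and 1.65% (1.14 to 2.31) in flox/null day 6. The Mmp9 and Ctsk cluster 7 held 2.65%, 4.54%, 2.65% and 2.15%. The cDC2-like cluster 10 held 1.85%, 1.42%, 4.20% and 2.61%. The 2-sided exact permutation p for genotype was 1 for clusters 3 and 7 and 0.667 for cluster 10; for day it was 0.333 for all 3, the smallest value that 2 mice against 2 allow. The T or NK-like and endothelial-like clusters were too small to compare.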

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

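The tests of patterns in this part were all chosen after the results were seen, and so was the limit of log2 0.2 on a list's median at each day.

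Type I interferon genes stood out because flox/null cells lay above wt/null cells at day 5 and below them at day 6, with list medians of log2 0.57 and −0.36. At day 5 all 21 members were higher and at day 6 only 1 was. Muscle and blood transcripts stood out in the opposite order, with medians of −0.38 at day 5 and 0.84 at day 6; the list holds transcripts of muscle fibres and blood cells, which the sort excludes. The difference between the days was not tested in either case, since each day holds 1 mouse per genotype. Transcripts of the CreERT2 transgene stood out as a signal outside the comparisons, with 38 counts over all cells and some in every mouse.

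Genotype differences of opposite sign at day 5 and day 6 were weighed as a pattern. Another mix of clusters in each mouse stays open. With the same number of cells per cluster in every mouse, the correlation across genes of the 2 differences was −0.0428 (Spearman's rho −0.0415, same sign for 48.2% of genes), against −0.0977 (rho −0.180, 43.3%) over all summed cells, so much of the pattern may come from the mix. Fewer cells also add counting noise, which moves such a correlation towards 0 as well. Type I interferon genes reversed inside single clusters too, with medians of 0.67 at day 5 and −0.55 at day 6 in cluster 2. They were 0.42 and −0.62 in cluster 5 and 0.39 and −0.18 in cluster 9, but 0.57 and 0.07 in cluster 1 and 0.52 and −0.01 in cluster 0. For these genes this argues against the mix of the clusters as drawn here as the whole cause. The clusters were computed without these genes, so interferon-responding cells can lie inside any of them. The cluster led by Ifit2, Ifit3 and Cxcl10 held 392 cells, but 718 with interferon and MHC genes kept in the clustering. Another mix of interferon-responding cells inside the clusters therefore stays open. Differences between mice other than genotype and day also stay open. When wt/null day 5 and flox/null day 6 were set against the other 2 mice, 468 genes had an unadjusted p below 0.05, against 283 for the genotype split fitted in the same way, and 0 passed in either. With 1 mouse per genotype and day, a true dependence of the genotype effect on day and chance differences between mice cannot be told apart, and the biological explanation was not tested.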

How the results depend on the processing

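The alternatives with other clustering seeds or the distance-weighted graph, without the highest Scrublet scores, with the same cluster mix, without the immediate early gene cluster or the Ly6c2 cluster, with DESeq2 inside clusters, and with mice left out for lists and clusters were chosen after the results were seen.

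The count of genes called by genotype (0) was 11 with DESeq2, 72 with no filter on low counts, 2 with the 80% hash rule, 3 with stricter cell filters, 2 with all single-hash cells, 1 with the same number of cells per mouse and 6 with interferon and MHC genes kept in the clustering. It was 6 without the highest Scrublet scores, 2 and 50 with other seeds, 3 with the distance-weighted graph, 7 with the same cluster mix and 30 without the immediate early gene cluster. It was 0 to 59 with each mouse left out, 0 with DESeq2 size factors, with no day term and without the Ly6c2 cluster. The count by day (0) was 16 with DESeq2, 145 with no filter, 1 with stricter filters, 1 with the same number of cells, 18 with interferon genes kept, 4 without the highest Scrublet scores, 152 with a further seed, 1 with the same cluster mix, 75 without the immediate early gene cluster and 0 to 103 with each mouse left out. edgeR's prior degrees of freedom were 4.65 in the main test, 24.4 with no filter and 14.5 with the further seed. With the further seed, clusters of 1138 cells (led by Gdf15 and Fosb) and 712 cells (led by Acta1 and Mylpf) stayed unnamed. Their cells were left out of the sums, so the counts of 50 and 152 rest on another set of cells. Whether this raised the counts was not tested, nor was the cause of the other changes.

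Lists called by genotype (4) were 0 with an estimated correlation, 0 with fry and 3 to 7 with each mouse left out. Lists called by day (8) were 0, 0 and 4 to 7, 5 with no genotype term and 4 with the same cluster mix. With an estimated correlation the test had 1 residual degree of freedom, so the 0 for each contrast could hardly have come out otherwise. Cell cycle genes by genotype reversed with all single-hash cells (camera adjusted p = 0.00505). Fits with a mouse left out had no term for the other factor, so a reversal there can come from that factor. With a mouse left out, a reversal came for these lists, given as the range of adjusted p: by genotype, type I interferon 2.9e-06 to 0.165, MHC class II 0.00403 to 0.971, Ly6c-high monocyte 5.5e-08 to 0.442 and hypoxia 9.7e-04 to 0.691; by day, IFNγ response 8.3e-08 to 0.212, type I interferon 0.00781 to 0.295 and stress 7.2e-11 to 0.189. The cause was not tested.

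Genes called within clusters (95 in sum) were 55 at lower resolution, 231 with a further seed, 169 with the distance-weighted graph, 19 with DESeq2 and 22 to 599 with each mouse left out. Cell classes whose share differed with the same sign at both days (2) were 4 with interferon and MHC genes kept, 4 with the 80% hash rule and 4 with stricter filters. With stricter filters a cluster of 894 cells led by Mmp12, Spp1 and Fabp4 was named Ly6c-high monocyte-like. Classes therefore did not hold the same cells under each setting. The cause of these changed counts was not tested. Named genes kept their side of the threshold in 1598 of 1760 values under these alternatives and passed it anew in 162. Their sign changed in 99, 58 of them with a mouse left out, and 0 of those 99 passed the threshold in either test. Scrublet doublets could not be left out as planned, because its threshold called none. Day, which goes with the replicate number, was already a block in the main model. Depth limits genes of a few CPM, such as Cdk5rap1 and E230001N04Rik, and Retnla in flox/null day 6, which rests on 2 counts.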

Other observations

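The tests in this part, the lists of glucocorticoid-induced genes and the comparison of clusterings were all chosen after the results were seen.

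Higher pro-inflammatory genes in flox/null mice on both days were weighed as a pattern. In this paragraph ± is a standard error over the genes of a list and holds no spread between mice. Stress during tissue dissociation is argued against as the whole cause for the day 5 pair of mice. At that day the stress genes had a median log2 change of 0.017 ± 0.056, while the pro-inflammatory genes had 0.489. At day 6 the stress genes had 0.564, so for that day alone stress stays open. Another mix of clusters stays open: with the same number of cells per cluster in every mouse the list's median was 0.517 ± 0.315, against 0.730 over all cells, so a part of the difference may come from the mix. The hypothesis that flox/null mice had met less glucocorticoid was raised by the lower Tsc22d3, Ddit4 and Fkbp5. It was tested on 13 glucocorticoid-induced genes whose values had not been looked at: their median was −0.0034 ± 0.138, and 7 were lower, which decides nothing. In the resident macrophage-like cluster 9 the median of the 9 measured there was −0.26 ± 0.13, with 6 lower (camera p = 0.0227, and 0.390 with an estimated correlation). In clusters 0, 1, 2 and 5 the medians lay near 0, at −0.04, 0.0016, −0.04 and −0.01, although Tsc22d3 passed its test in 3 of them. The camera p was 0.985 in cluster 1, 0.739 in cluster 2 and 0.537 in cluster 5. In cluster 0 the medians by day were −0.56 at day 5 and −0.22 at day 6 (camera p = 0.0702, and 0.461 with an estimated correlation). The hypothesis of less glucocorticoid stays open. The 6 genes of this kind whose values had been seen before had a median of −0.69, with Fkbp5 at −1.06, Klf9 at −0.53, Per1 at −0.26 and Dusp1 at −0.01; they are no independent test. The design's own explanation, loss of IFNγ signalling in the Cx3cr1 lineage, was not tested and stays open. A loss of this signalling is not shown by these data. IFNγ-induced genes were not lower in flox/null mice (median 0.14, 28 of 33 higher), and MHC class II genes had a median of −0.02. The level of Ifngr1 does not check the deletion. With 2 mice per genotype, this explanation cannot be separated from differences between mice.

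Across 5 clusterings (the main one, a lower resolution, 2 other seeds and the distance-weighted graph), Tsc22d3 was lower in every tested macrophage-like, resident macrophage-like and cDC2-like cluster, from log2 −0.46 to −1.31, and Cdk5rap1 was higher in every one, from 1.44 to 2.87. Cluster 1 of the distance-weighted graph, counted here as macrophage-like, was led by the muscle transcripts Acta1, Mylpf and Myl1. Retnla in resident macrophage-like cells lay between −3.34 and −3.72 and Ccl17 in cDC2-like cells between −2.98 and −3.31, but not every call held. At the lower resolution the resident macrophage-like cluster had 0 genes called, with edgeR adjusted p of 0.338 for Retnla, 0.561 for Cxcl10, 0.592 for Cxcl2, 0.471 for Tsc22d3 and 0.446 for Ddit4. Cxcl10 was at 2.93 there, Cxcl2 at 0.99 and Ddit4 at −2.60; the cluster had 306 cells and 7.70 prior degrees of freedom, against 596 and 27.1 in the main clustering. Tsc22d3 also missed the threshold in a further cluster of the lower resolution (0.0804), in 1 of a further seed (0.0508) and in 1 of the distance-weighted graph (0.321), and Ccl17 in 1 of the 2 cDC2-like clusters of that graph (0.0742). Cxcl9, higher over the summed cells, passed the threshold in both directions in macrophage-like clusters. It fell at the lower resolution (−2.29, edgeR adjusted p = 0.00130) and with a further seed (−2.69, 0.0368), and rose with another seed (2.12, 0.0282) and with the distance-weighted graph (4.30, 1.4e-27). A fall of Cxcl9 in cDC2-like cells, seen in the first clustering, did not hold: its log2 fold change was 0.38 ± 0.63 in the main clustering and 0.13 to 0.38 over the 5.

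Genes near Ifngr1 were looked at because a floxed allele brings the surrounding chromosome of the strain in which it was made. Of 57 tested genes within 10 Mb, 5 had an unadjusted p below 0.05 (8.77%, against 3.15% of all tested genes): Stxbp5, Fbxo30, Gm10827, 1700020N01Rik and Arg1. Arg1, an enzyme of arginine breakdown in alternatively activated macrophages, was at 2.18 CPM in wt/null and 8.78 in flox/null at day 5 and at 1.66 and 2.76 at day 6 (log2 1.48 ± 0.32). Strain variants were not examined here.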
